A study of Mus musculus with 6 samples.

How the data were processed

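RNA of 6 MC3T3-E1 cultures was hybridized to single-colour (Cy3) NimbleGen expression arrays, 1 array per culture. Per the labels, RNA was isolated with a guanidine-phenol reagent and amplified by the array maker's methods. The cells grew in alpha MEM with 10% serum, and all cultures were treated with 100 nM 1,25(OH)2D3 for 24 h. The groups were taken from the sample titles, with 3 undifferentiated arrays and 3 arrays of cells differentiated for 15 days. The deposited values are linear expression intensity per feature, made by the authors with RMA, per the submitters' processing notes. RMA corrects background, normalizes probes between arrays and summarizes them per feature, but its version, the arrays it was run on together, the genome build and the annotation are not given in the sources used here. Per the file headers, each file gives a feature identifier, its number of probes and its expression value. Of the 42586 features, 42566 had 9 probes and 20 had fewer, and 1 control feature of 6131 random probes was kept out of all tests. A deposited table of the whole series held the same values, with a largest difference of 0, so using it in place of the array files changes nothing. It had 0 columns of other series. The upper quartile of the log2 values was 11.46 and 11.39 in undifferentiated replicates 1 and 2 and 11.26 to 11.30 on the other 4 arrays, so the deposited distributions were not identical. Log2 was taken of the authors' intensity values, with no further normalization in the main analysis.

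Features were named by matching their RefSeq transcript identifiers, without versions, to a table of RefSeq genes (assembly GRCm38.p6) that was used for names only. A single symbol was found for 17849 features (41.9%), several for 0 and none for 24737. The named features gave 17298 genes. For the 467 genes with several features the feature with the highest mean log2 value over all arrays was used. In 2 of these genes features passed in opposite directions, and in 104 only some features passed. Features without a symbol changed about as often, 4878 of 24737 against 3487 of 17849 with one.

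Differences are differentiated minus undifferentiated on the log2 scale. They were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all features or all genes, and called at an adjusted p under 0.05, for the 2-fold counts with a log2 difference of at least 1 in size. A gene was taken as at or below the random probes in a group when all 3 arrays of the group had it at or below that array's control feature. Where this held for 1 group, the fold is given as a lower bound, from the bright group's mean over the dim group's mean of, per array, the higher of the control feature and the gene's own value. Where it held for both groups, as for 795 genes of which 1 was called, no fold is given. Precision is limited by 3 arrays per group, and the spread between arrays is the only error that enters the tests.

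The 27 gene lists and the rule for named genes were fixed before the data were examined, from general knowledge of osteoblasts and vitamin D, and 526 of their 544 members were measured. The rule takes 16 fixed genes, the 8 largest increases and 8 largest decreases among called genes with non-overlapping groups (clone and predicted names left out), and up to 4 called members of each list, and it named 113 genes. A member outside the rule that completes a count of 5 or fewer was chosen after its values were seen. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 with Benjamini-Hochberg adjustment over the 27 lists, with camera at an estimated correlation, and with fry. Camera compares a list with the other genes, whereas fry tests whether its genes move one way on balance. None of the 6 lists called by camera was called with an estimated correlation, while fry called 19 lists, 16 upward and 3 downward.

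The tests were first run on simulated arrays with the spread of these arrays. Of 50 genes changed by a log2 value of 0.5 in a set of 17298, 6% were recovered, of those changed by 1, 58%, of those changed by 2, 96%, and of those changed by 3, 100%, with 1 false call. Over 42586 features the shares were 0%, 54%, 96% and 96%, with 7 false calls. Only 50 genes or features of each size were changed there, against 3367 genes and 8365 features called on the real arrays. With fewer changes the Benjamini-Hochberg adjustment is stricter, so these shares may understate recovery on the real arrays. Camera made a call in 1 of 20 draws with no change. Genes varied independently in those draws, so they do not show how often camera calls lists whose genes vary together. On the real arrays the estimated correlation ran from -0.0437 (osteocyte markers) to 0.505 (cell cycle). Alternatives fixed beforehand were quantile normalization, equal array medians, cyclic loess, 2 filters on dim features, the replicate number as a block, the array number start as a covariate, an intensity trend with a robust prior, array weights, a test against 1.5-fold, the mean over a gene's features, and leaving out each array in turn. A filter on features above the random probes was added after the data were seen. Computations in Python 3.11.15 used pandas 2.3.3 and numpy 2.4.6, and figures used matplotlib 3.10.9.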

Results

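Gene expression was measured on 6 single-colour NimbleGen arrays in MC3T3-E1 cells, a mouse pre-osteoblast line from newborn calvaria that forms a mineralizing matrix when given ascorbic acid and a phosphate source. All 6 cultures received 100 nM 1,25-dihydroxyvitamin D3 (1,25(OH)2D3), the hormonal ligand of the vitamin D receptor, for 24 h. The undifferentiated group held 3 arrays, and the differentiated group held 3 arrays of cells kept for 15 days with 10 mM glycerol-2-phosphate and 50 µg/mL ascorbic acid. The labels give the samples as biological triplicates at passages 5 to 12. Arrays of vehicle-treated cells were not analysed here, so the values describe how differentiated and undifferentiated cells differed under the hormone and give no response to it. Each array carried 42586 features of mostly 9 probes, with a median expression value of 793 to 835 on the linear scale. The control feature of 6131 random probes read 96.3 to 112, and 5.61% to 6.80% of features lay below it. Between arrays, Pearson's r across features was 0.992 to 0.996 within the differentiated group, 0.979 to 0.994 within the undifferentiated group and 0.958 to 0.978 between the groups. Features are not independent replicates, so these coefficients describe the arrays only. Undifferentiated replicate 3 stood apart from replicates 1 and 2 of its group and lay nearer the differentiated arrays.

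**Figure D1:**
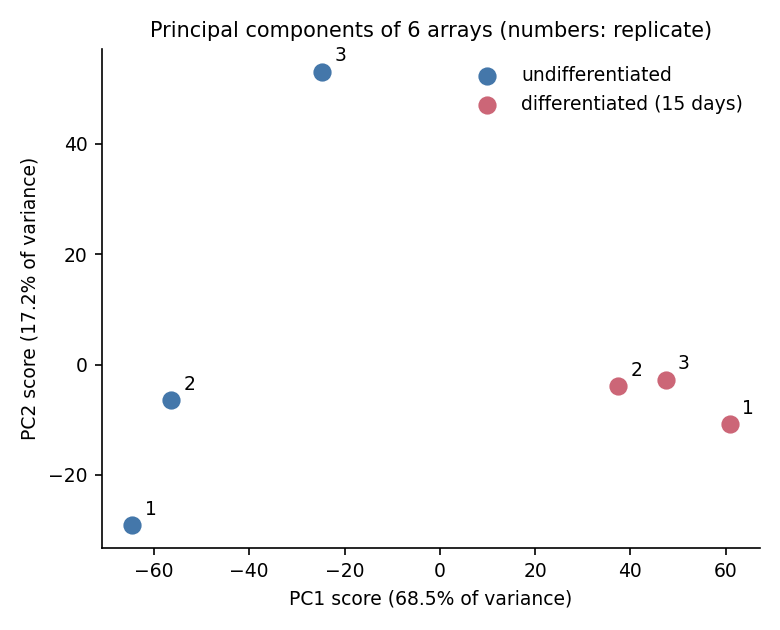
Scores of the 6 arrays on the first 2 principal components of the log2 expression values, coloured by group and numbered by replicate. The first component (68.5% of the variance) separated the groups, and the second (17.2%) set undifferentiated replicate 3, at 53.1, apart from the other 5 arrays, all below 0.

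The comparison of differentiated with undifferentiated cells addressed how the transcriptome of hormone-treated cells changed over osteoblast differentiation. Differentiated cells carried far more transcript of the mineralization enzyme Alpl, of the growth factor Igf2 and of the matrix genes Col15a1, Lum and Itgbl1. They carried less transcript of the vitamin D receptor itself, of proliferin family genes and of cholesterol synthesis enzymes. Collagens other than type I, small leucine-rich proteoglycans, and skeletal muscle and endothelial marker genes shifted upward as lists, while cholesterol synthesis and cell cycle genes shifted downward. None of these 6 shifts passed with an estimated correlation (adjusted p = 0.403 to 0.566). In the limma moderated test with Benjamini-Hochberg adjustment, 3367 of 17298 named genes changed at an adjusted p under 0.05. Of these, 1485 were higher and 1882 lower in differentiated cells, and 6366 genes had an unadjusted p under 0.05. A change of at least 2-fold was seen for 617 genes, 219 higher and 398 lower. Over all features, 8365 of 42586 changed, 3396 higher and 4969 lower, and 1620 changed at least 2-fold. With every array shifted to the same median, 34.1% of the changed genes were higher in differentiated cells, against 44.1% with the deposited values. The share was 57.4% with array weights (4838 higher, 3594 lower) and 55.1% without undifferentiated replicate 3 (4286 higher, 3491 lower). Without a fold limit the excess of lower genes was thus not kept. At 2-fold it was, with 232 higher and 463 lower under array weights and 250 higher and 553 lower without that replicate. The groups did not overlap for 6937 genes, 40.1% of all genes. For a single gene, chance gives 10% with 3 against 3 arrays. Genes on an array vary together and image date followed the groups, so the excess does not tell differentiation from a shift shared by the arrays of a group. The count of changed genes depended on single arrays. It was 7777 without undifferentiated replicate 3, 1354 without differentiated replicate 1, 1496 without undifferentiated replicate 2, 1647 without differentiated replicate 3 and 2033 without differentiated replicate 2. The count at 2-fold lay between 524 and 803 over these settings.

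Among components of the vitamin D pathway, Vdr, which encodes the hormone's receptor, fell from a log2 expression value of 12.48 ± 0.41 to 10.75 ± 0.41 (SD, n = 3 each), a 3.31-fold decrease (adjusted p = 0.000835). Its partner Rxra differed by -0.53 without passing the test (adjusted p = 0.275). Its values were 10.31 and 9.87 in undifferentiated replicates 1 and 2 and 8.59 in replicate 3. Without replicate 3 the difference was -1.03 (adjusted p = 5.22e-05, with a range of 5.22e-05 to 0.725 over the settings run). With the array number start as a covariate, which leaves replicate 3 as the undifferentiated array compared, the difference turned to 0.47. Cyp24a1, the hormone-degrading 24-hydroxylase and a classical target of the receptor, differed by -0.10 (adjusted p = 0.863). Differentiated replicate 3 carried 9.84 for Cyp24a1 against 8.09 and 8.35 in replicates 1 and 2, and without it the difference was -0.64 (adjusted p = 0.0496, with a range of 0.0496 to 0.999 over the settings run). Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, differed by -0.09 (adjusted p = 0.643), and its decoy receptor gene Tnfrsf11b by 0.27 (adjusted p = 0.171). Tnfrsf11b passed in 1 of 18 settings, array weights (adjusted p = 0.0147, with a range up to 0.41 over the settings run). Of 23 measured members of the list of the receptor and its known targets, 7 rose, 1 fell and 15 did not pass, and the counts were the same adjusted over the list alone. The collagenase gene Mmp13 rose 4.21-fold (adjusted p = 1.04e-05), the parathyroid hormone receptor gene Pth1r rose 2.49-fold (adjusted p = 0.000106), and Bglap, the osteocalcin gene, rose 2.14-fold (adjusted p = 0.00338). The member that fell was Vdr. The list's upward shift did not pass in camera (adjusted p = 0.138, with a range of 0.047 to 0.256 over the settings run), whereas fry gave an adjusted p of 0.007.

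Genes of bone matrix and mineralization rose in part. Of 20 measured, 6 rose, none fell and 14 did not pass, with the same counts adjusted over the list alone. Alpl, the tissue-nonspecific alkaline phosphatase that releases phosphate for mineral, rose from 9.24 ± 0.15 to 12.94 ± 0.06 (SD, n = 3 each), or 12.96-fold (adjusted p = 6.79e-08). Phospho1, a phosphatase of matrix vesicles, rose 2.35-fold (adjusted p = 0.00598). Bglap has near-identical neighbours in the mouse genome, Bglap2 and Bglap3, so its value is uncertain as that of a single gene. Col1a1 differed by 0.07 (adjusted p = 0.698), but no named gene was brighter in its mean over the arrays. At 15.86 in undifferentiated cells it lay near the top of the scale. Spp1, the osteopontin gene, differed by -0.32 (adjusted p = 0.132), and Ibsp, the bone sialoprotein gene, by 0.11 (adjusted p = 0.679) at a level close to the random probes. Spp1 passed in 2 of 18 settings, array weights and without undifferentiated replicate 1 (adjusted p from 0.00874 to 0.341 over the settings run), and Ibsp in 1 of 16, array weights (adjusted p = 0.024, with a range up to 0.946). The list's upward shift did not pass (camera adjusted p = 0.0702), though it did in 5 of 16 settings, with adjusted p from 0.0247 to 0.115. Of 10 osteocyte genes, 1 rose, 1 fell and 8 did not pass, against 3 and 1 adjusted over the list alone (camera adjusted p = 0.662). Dmp1, an acidic phosphoprotein of the bone matrix, rose 4.64-fold (adjusted p = 0.000272), and the hyaluronan receptor gene Cd44 fell 1.67-fold (adjusted p = 0.00744). Phex, a peptidase of phosphate regulation, was at or below the random probes in both groups. Of 20 osteoblast transcription factors, 3 rose, 6 fell and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.164). Sp7, the osterix gene required for osteoblast formation, rose 1.62-fold (adjusted p = 0.0163). It did not pass in 2 of 17 settings, without differentiated replicate 1 and without differentiated replicate 2. Without replicate 1 its adjusted p was 0.0693, the highest of a range from 0.0027 over the settings run. Lef1, a nuclear effector of Wnt signalling, rose 2.09-fold (adjusted p = 0.000617). The AP-1 subunit genes Fosl1 and Fosl2 fell 3.28-fold (adjusted p = 0.000668) and 1.82-fold (adjusted p = 0.00597), and the homeobox gene Msx2 fell 2.01-fold (adjusted p = 0.000343). Runx2, the master regulator of the lineage, differed by 0.09 (adjusted p = 0.658), and Cebpb by 0.16 (adjusted p = 0.376).

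**Figure D2:**
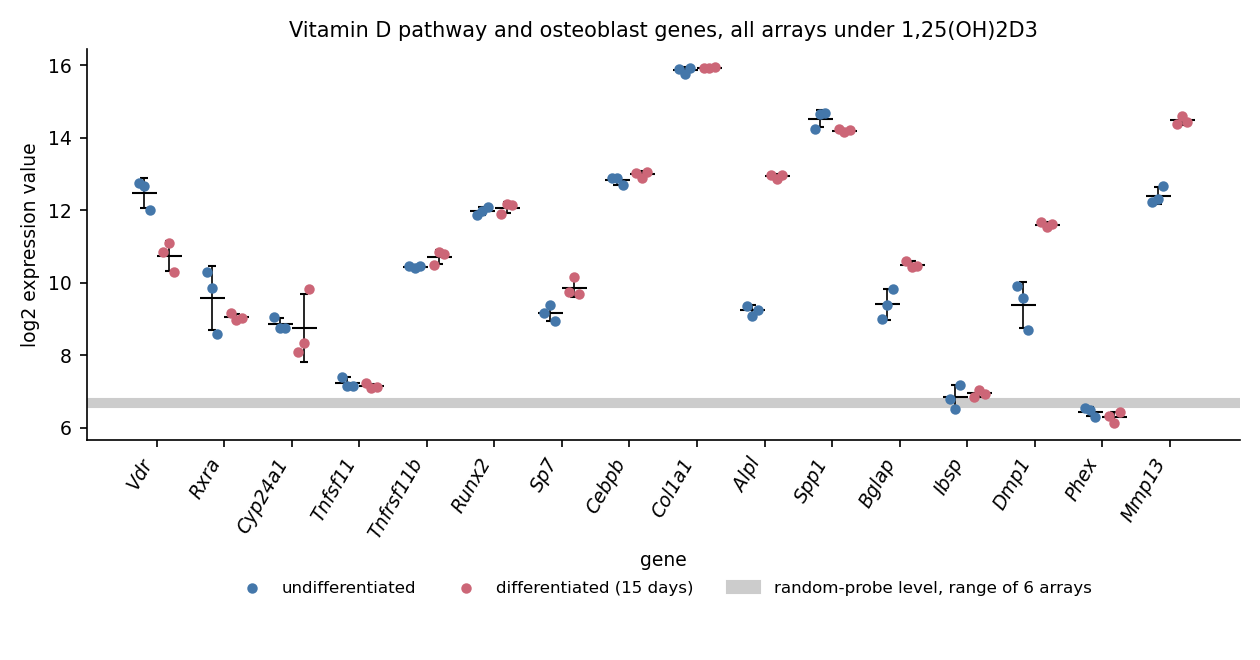
Log2 expression values of 16 vitamin D pathway and osteoblast genes fixed before the data were examined, with 1 point per array, bars for the mean ± SD (n = 3) and a grey band for the random-probe level. Alpl, Dmp1 and Mmp13 were higher in all 3 differentiated arrays and Vdr was lower, while Cyp24a1 had 1 differentiated array at 9.84 and Rxra 1 undifferentiated array at 8.59.

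Collagens other than type I differed in both directions. Of 22 measured, 11 rose, 1 fell and 10 did not pass, against 12 and 3 adjusted over the list alone, with a median log2 difference of 0.42. The list shifted upward (camera adjusted p = 0.00919; adjusted p = 0.403 with an estimated correlation). Col15a1, a basement membrane-associated collagen chain, rose 28.73-fold (adjusted p = 6.79e-08), the fibril-regulating Col11a1 rose 5.41-fold (adjusted p = 1.17e-05), and Col18a1, the precursor of endostatin, rose 3.07-fold (adjusted p = 2.03e-05). Col5a2, a fibrillar chain of type V collagen, fell 2.98-fold (adjusted p = 0.000328). Small leucine-rich proteoglycans, which bind and space collagen fibrils, also shifted upward (camera adjusted p = 0.0113; adjusted p = 0.403 with an estimated correlation). Of 12 measured, 5 rose, none fell and 7 did not pass, and 6 rose adjusted over the list alone. Lum, the lumican gene, rose 11.59-fold (adjusted p = 1.77e-07), Podn rose 1.96-fold (adjusted p = 0.0031) and Dcn, the decorin gene, rose 1.57-fold (adjusted p = 0.0061). Without differentiated replicate 2 this list's adjusted p was 0.0531, the highest of a range from 0.00388 over the settings run. Among 22 genes of collagen processing and crosslinking, 2 rose, 3 fell and 17 did not pass, against 2 and 4 adjusted over the list alone. The prolyl hydroxylase gene P4ha3 rose 2.07-fold (adjusted p = 0.00175), while the crosslinking oxidase gene Lox fell 2.08-fold (adjusted p = 0.000624). The median of this list, 0.05, and its mean, 0.04, were positive, whereas its camera direction was downward (adjusted p = 0.938). Of 24 matrix metalloproteinases and inhibitors, 4 rose, 1 fell and 19 did not pass, against 5 and 1 adjusted over the list alone (camera adjusted p = 0.135). Besides Mmp13, the aggrecanase gene Adamts4 rose 2.37-fold (adjusted p = 0.000342), and Mmp19 fell 1.87-fold (adjusted p = 0.00298).

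Secreted regulators of growth factor signalling included some of the larger changes. In the IGF system, 6 of 14 genes rose, 2 fell and 6 did not pass, the same adjusted over the list alone. The growth factor genes Igf2 and Igf1 rose 10.80-fold (adjusted p = 2.2e-07) and 2.96-fold (adjusted p = 3.13e-05), and Igfbp5, a binding protein stored in bone matrix, rose 3.67-fold (adjusted p = 3.32e-05). Pappa, a protease that frees IGF from its binding proteins, fell 2.51-fold (adjusted p = 0.00129). The list's shift did not pass (camera adjusted p = 0.0702), but it did in 6 of 16 settings, with adjusted p from 0.00814 to 0.109, among them quantile normalization (0.0421) and cyclic loess (0.0264). Of 38 Wnt pathway genes, 7 rose, 4 fell and 27 did not pass, the same adjusted over the list alone (camera adjusted p = 0.127). The 3 with the largest rises encode secreted antagonists or modulators of the pathway. Sfrp2 rose 5.72-fold (adjusted p = 3.22e-06), Sostdc1 rose 5.57-fold (adjusted p = 1.46e-06) and Dkk2 rose 3.49-fold (adjusted p = 1.6e-05). Ccn5, also known as Wisp2, fell 4.62-fold (adjusted p = 0.000125). Of 35 BMP and TGF-beta pathway genes, 6 rose, 4 fell and 25 did not pass, against 7 and 4 adjusted over the list alone (camera adjusted p = 0.26). The bone morphogenetic protein gene Bmp4 rose 2.78-fold (adjusted p = 0.000115) and Tgfb2 rose 1.74-fold (adjusted p = 0.00634), while Bmper, which encodes a BMP-binding regulator, fell 4.34-fold (adjusted p = 2.25e-05).

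Cholesterol synthesis genes shifted downward as a list. Of 23 measured, none rose, 11 fell and 12 did not pass, against 14 that fell adjusted over the list alone, with a median log2 difference of -0.57. The downward shift had a camera adjusted p of 1.59e-07 (adjusted p = 0.403 with an estimated correlation). Sc5d, a late-pathway desaturase gene, fell 2.41-fold (adjusted p = 0.000361), the isopentenyl diphosphate isomerase gene Idi1 fell 2.35-fold (adjusted p = 0.00239) and the lanosterol synthase gene Lss fell 2.04-fold (adjusted p = 0.0014). Undifferentiated replicate 3 itself lay below replicates 1 and 2 on this list, with a median difference of -0.37, and differentiated cells lay below replicate 3 with a median of -0.33. Without replicate 3, 18 of the 23 genes fell. Cell cycle genes shifted downward as well in camera (adjusted p = 0.00919, and 0.566 with an estimated correlation). Fry did not call this list (adjusted p = 0.292). Of 32 measured, none rose, 8 fell and 24 did not pass, the same adjusted over the list alone. The cyclin genes Ccna2 and Ccnb1 fell 2.56-fold (adjusted p = 0.00574) and 2.44-fold (adjusted p = 0.00768), and the spindle-associated Nusap1 fell 2.11-fold (adjusted p = 0.0123; up to 0.0607 in 1 of 17 settings). The list's median was -0.15, and undifferentiated replicate 3 lay at -0.22 relative to replicates 1 and 2. The median was -0.05 after quantile normalization and -0.10 after cyclic loess. The camera call ended in 4 of 16 settings, among them cyclic loess (adjusted p = 0.0524) and without differentiated replicate 1 (0.0749). Over the settings run the camera adjusted p ranged from 5.29e-06 to 0.268. Of 23 glycolysis and hypoxia genes, 1 rose, 2 fell and 20 did not pass, against 1 and 4 adjusted over the list alone (camera adjusted p = 0.65). The carbonic anhydrase gene Car9 rose 2.82-fold (adjusted p = 9.08e-05), and Ddit4, a stress-induced inhibitor of mTOR, fell 1.99-fold (adjusted p = 0.00717; up to 0.0543 in 1 of 17 settings). Of 24 amino acid and unfolded protein stress genes, 1 rose, 2 fell and 21 did not pass, the same adjusted over the list alone (camera adjusted p = 0.283), and the asparagine synthetase gene Asns fell 3.04-fold (adjusted p = 4.87e-05).

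Genes of cytokines and inflammation moved in both directions. Of 24 inflammatory and acute-phase genes, 4 rose, 6 fell and 14 did not pass, against 7 and 6 adjusted over the list alone. The alarmin gene Il33 rose 14.12-fold (adjusted p = 1.38e-07), while the haptoglobin gene Hp fell 3.07-fold (adjusted p = 0.00117) and the chemokine gene Cxcl5 fell 2.78-fold (adjusted p = 0.000302). The list's median, 0.11, and mean, 0.06, were positive, and its camera direction was downward (adjusted p = 0.938). Of 14 osteoclast-regulating factors, 1 rose, 3 fell and 10 did not pass, against 2 and 4 adjusted over the list alone. The ephrin gene Efnb2 fell 6.75-fold (adjusted p = 3.93e-07), Ptgs2, the inducible cyclooxygenase gene, fell 3.04-fold (adjusted p = 0.000228), and Il6 rose 1.75-fold (adjusted p = 0.00334). The median of this list was 0.11, its mean -0.21 and its camera direction downward (adjusted p = 0.425). Of 23 interferon-stimulated genes, 1 rose, 4 fell and 18 did not pass, the same adjusted over the list alone. The guanylate-binding protein gene Gbp2 fell 1.86-fold (adjusted p = 0.00131), and Ifit3 rose 1.76-fold (adjusted p = 0.0122; not passed in 2 of 18 settings, up to 0.0739). Here the median was 0.02 and the mean -0.07, with a downward camera direction (adjusted p = 0.364).

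Wide differences were found in genes of varied function. Cd200, which encodes an immunoregulatory membrane glycoprotein, was at or below the random probes in undifferentiated cells and at least 31.4-fold higher in differentiated cells (adjusted p = 3.86e-07). Itgbl1, a secreted protein with integrin-like repeats, rose 35.92-fold (adjusted p = 6.79e-08), F13a1, the factor XIII transglutaminase subunit, 18.81-fold (adjusted p = 9.99e-07), and Ackr4, a chemokine-scavenging receptor, 15.22-fold (adjusted p = 6.79e-08). Adh1, an alcohol dehydrogenase, rose 15.05-fold (adjusted p = 8.84e-08) and Fmo1, a flavin-containing monooxygenase, rose 13.20-fold (adjusted p = 6.52e-07). Prl2c2, Prl2c3 and Prl2c5, proliferin genes of the prolactin family, were at or below the random probes in differentiated cells and at least 17.3-fold, 16.8-fold and 10.3-fold lower (adjusted p = 6.79e-08, 8.84e-08 and 9.11e-06). These genes are near-identical copies, so their values are uncertain as those of single genes. Fam110c fell 18.02-fold (adjusted p = 2.14e-07), the guidance ligand gene Sema3e fell 14.72-fold (adjusted p = 1.46e-06), the platelet basic protein chemokine gene Ppbp fell 14.19-fold (adjusted p = 9.72e-08), the kinase-like gene Styk1 fell 14.09-fold (adjusted p = 6.79e-08), and the chemokine receptor gene Cxcr6 fell 8.85-fold (adjusted p = 1.46e-06).

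Marker genes of other cell types were measured in the same arrays. Of 14 skeletal muscle genes, 4 rose, none fell and 10 did not pass, and 7 rose adjusted over the list alone. The list shifted upward (camera adjusted p = 0.00919; adjusted p = 0.403 with an estimated correlation), with a median of 0.43. Tnni2, Tnnc2 and Tnnt3, fast-muscle troponin genes, rose 1.65-fold (adjusted p = 0.0326), 1.63-fold (adjusted p = 0.0299) and 1.49-fold (adjusted p = 0.0234), and the other was Ckm. Undifferentiated replicate 3 lay above replicates 1 and 2 by a median of 0.32 on this list. With the array number start as a covariate, which leaves replicate 3 as the undifferentiated array compared, none of the 14 passed and the list's adjusted p was 0.255, the highest of a range from 0.00367 over the settings run. The list's median was 0.21 there, still positive, with fewer arrays to test it. Over the settings run, Tnni2 did not pass in 6 of 18 (adjusted p up to 0.427), Tnnc2 in 5 (up to 0.29) and Tnnt3 in 4 (up to 0.113). Of 12 endothelial genes, 4 rose, none fell and 8 did not pass, and 5 rose adjusted over the list alone. The list shifted upward (camera adjusted p = 0.0403; adjusted p = 0.403 with an estimated correlation) with a median of 0.33. The VEGF receptor gene Flt1 rose 4.56-fold (adjusted p = 0.000202), the angiopoietin receptor gene Tek rose 2.08-fold (adjusted p = 0.0033) and Esam rose by 0.48 on the log2 scale (adjusted p = 0.0263), although it did not pass in 5 of 17 settings (adjusted p up to 0.128). After quantile normalization the endothelial list's adjusted p was 0.11, and it ranged from 0.0313 to 0.148 over the settings run. Undifferentiated replicate 3 lay above replicates 1 and 2 by a median of 0.08 on this list, and differentiated cells lay above replicate 3 by 0.16. Of 17 chondrocyte genes, 6 rose, 2 fell and 9 did not pass, against 8 and 2 adjusted over the list alone (camera adjusted p = 0.0955). The chondromodulin gene Cnmd rose 4.88-fold (adjusted p = 1.34e-05), and the cartilage master regulator Sox9 fell 1.45-fold (adjusted p = 0.0274), although it did not pass in 7 of 18 settings (adjusted p up to 0.202). Of 16 adipocyte genes, 4 rose, 1 fell and 11 did not pass, against 9 and 2 adjusted over the list alone (camera adjusted p = 0.0738). The transcription factor gene Cebpa rose 2.68-fold (adjusted p = 7.1e-05), and Acsl1, a fatty acyl-CoA synthetase gene, fell 3.63-fold (adjusted p = 0.000242). Of 16 macrophage and osteoclast genes, 3 rose, 1 fell and 12 did not pass, the same adjusted over the list alone (camera adjusted p = 0.135), and Ctsk, the collagen-degrading cathepsin K gene, rose 2.36-fold (adjusted p = 0.000242). Of 9 neural genes, 2 rose, none fell and 7 did not pass, and 3 rose adjusted over the list alone (camera adjusted p = 0.127), with the myelin protein gene Mbp up 2.08-fold (adjusted p = 0.00184). Of 10 epithelial genes, 2 rose, none fell and 8 did not pass, the same adjusted over the list alone (camera adjusted p = 0.131). The keratin gene Krt14 rose 1.64-fold (adjusted p = 0.0113; not passed in 2 of 18 settings, up to 0.0799), and undifferentiated replicate 3 lay above replicates 1 and 2 by a median of 0.44 on this list. Without replicate 3 the list's adjusted p was 0.0391, the lowest of a range up to 0.968 over the settings run. Of 14 contractile and smooth muscle genes, 2 rose, 3 fell and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.425). The smoothelin gene Smtn rose 1.98-fold (adjusted p = 0.00144), and the tropomyosin gene Tpm2 fell 1.77-fold (adjusted p = 0.00834; up to 0.0574 in 1 of 18 settings). Of 15 common reference genes, 1 fell and 14 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0738). The transferrin receptor gene Tfrc fell 2.25-fold (adjusted p = 0.000411).

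**Figure D3:**
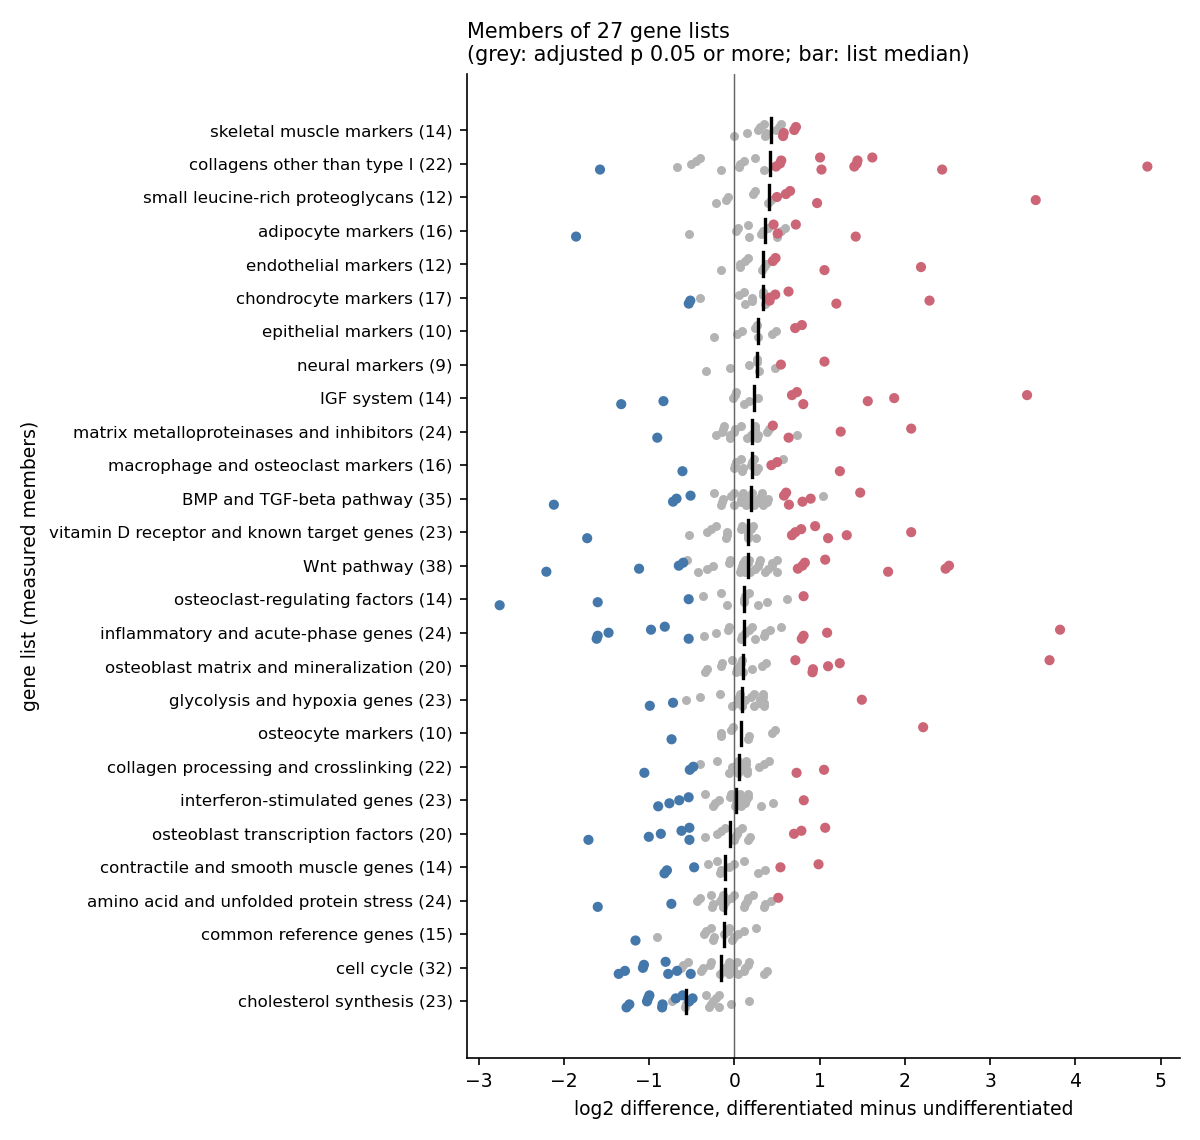
Log2 difference of differentiated minus undifferentiated cells for each measured member of 27 gene lists, with the list median as a black bar, members that rose in red, members that fell in blue and members that did not pass in grey. Cholesterol synthesis had the lowest median, -0.57, and skeletal muscle markers the highest, 0.43, while the members with the widest differences belonged to the collagens, the inflammatory genes and the bone matrix genes.

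Small differences followed the expression level of the genes. Genes were ranked by mean level into 10 equal groups, with 1 the dimmest. Groups 2 to 5 had median log2 differences of 0.17 to 0.23, and groups 7 to 10 of -0.04 to -0.10. After cyclic loess the medians of the 10 groups lay between 0.00 and 0.10. The image names carry 1 date token for each group, so image date and differentiation cannot be told apart. The array numbers start alike for undifferentiated replicates 1 and 2 and alike for the other 4 arrays. With that start as a covariate 3065 genes changed, of which 1921 were among the 3367.

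**Figure D4:**
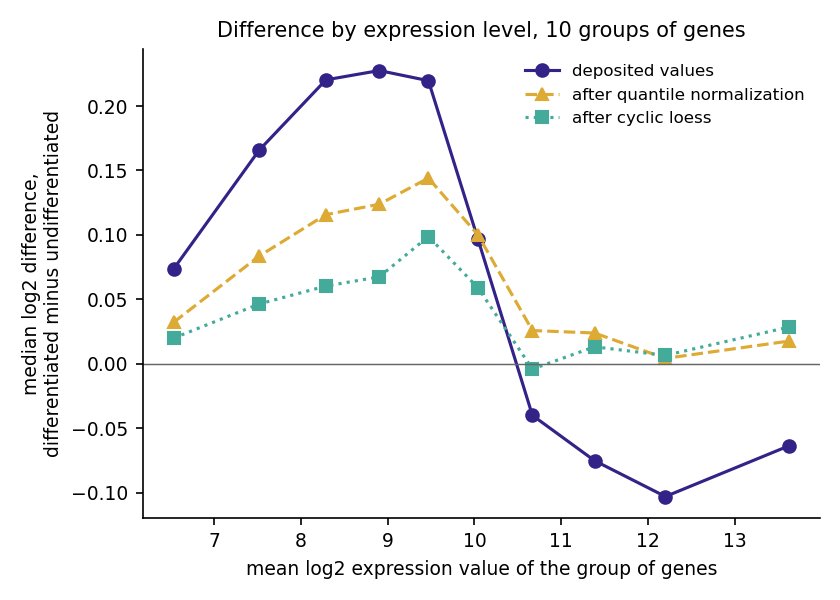
Median log2 difference of differentiated minus undifferentiated cells for 10 equal groups of genes ordered by mean log2 expression value, with the deposited values and after 2 other normalizations. With the deposited values the median reached 0.23 in group 4 and -0.10 in group 9, counted from the dimmest, and after cyclic loess it lay between 0.00 and 0.10.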

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

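Of the alternatives, only the filter on features above the random probes was chosen after the data were seen. The 2-fold counts were the steadiest. They stayed within 1.5 times of 617 genes and 1620 features in most settings. The exceptions were the filter above the median level (378 genes, 960 features) and the test against 1.5-fold (318 genes, 775 features). That filter left 8902 of 17298 genes and 21293 of 42586 features to test, whereas the test against 1.5-fold is stricter by construction. Above the median level, where fewer features were tested, 2205 genes and 5252 features changed. With gene-by-gene array weights the counts rose to 8432 genes, 21748 features and 270 list members, against 152 list members with equal weights; the cause was not tested. Leaving out each array in turn gave 1354 (without differentiated replicate 1) to 7777 genes (without undifferentiated replicate 3), 3371 to 18691 features and 81 to 248 list members for the same 2 arrays. The share of changed features that were higher was 40.6%, but 30.7% with equal array medians, 55.0% with array weights (11954 higher, 9794 lower) and 52.8% without undifferentiated replicate 3 (9871 higher, 8820 lower). Among features changed at least 2-fold it was 29.0%, and 24.2%, 27.7% and 26.8% in those settings. The 6 list shifts became 0 with an estimated correlation and 19 with fry. The replicate number as a replicate block gave 3452 genes and 8800 features. Same-numbered arrays deviated together with correlations of 0.01, 0.21 and 0.06, so the numbers were not read as pairs. The series value table changed nothing, being the same values.

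Of 103 named genes that were called, 71 passed in every setting run, among them 62 of the 64 that changed at least 2-fold. The other 2 were Matn4 and Nusap1. Named genes were not put through the test against 1.5-fold, and a gene left out by a filter was not counted in that setting. The rule names the largest called differences of these same arrays, so these shares do not describe 2-fold calls in general. All reversals were of values that did not pass, and their causes were not tested. With the array number start as a covariate Rxra stood at 0.47, Cyp24a1 at 0.00212, Runx2 at -0.0287 and Ibsp at -0.24. Cyp24a1 stood at 0.16 with array weights and between -0.64 and 0.24 with single arrays left out, and Ibsp between -0.0511 and 0.28. For lists, a reversal means that the camera direction turned. Collagen processing turned upward with medians of 0.10 after quantile normalization, 0.11 after cyclic loess, 0.0861 above the median level, 0.0861 with the dimmest features left out and 0.21 with the number start as a covariate, and its medians ran from -0.0142 to 0.15 with single arrays left out. Inflammatory genes turned upward at medians of 0.0569 with equal array medians and 0.11 with the dimmest features left out, and ran from 0.0443 to 0.18 with single arrays left out. Osteoclast-regulating factors turned upward at 0.15 above the median level and 0.12 with the dimmest features left out, and epithelial markers turned downward at a median of 0.00293 with the number start as a covariate. Signal over background limited the 795 genes at or below the random probes in both groups.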

Other observations

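Families of genes that share the start of their symbol were examined after the results were seen, and so were the tests of replicate 3 as a mixed or partly differentiated culture and by array number, the comparison with sensory receptor and beta-defensin genes, and the other splits of the arrays. Of 295 families with at least 8 measured genes, 20 shifted at a camera adjusted p under 0.05, and 0 did with an estimated correlation (adjusted p of at least 0.763). The families named here are examples and share no tested theme. Among 48 Rpl genes, which encode proteins of the large ribosomal subunit, 7 fell and none rose (median -0.21, adjusted p = 0.00178), and among 29 Rbm genes of RNA-binding proteins 11 fell and none rose (median -0.24, adjusted p = 0.0028). Of 36 Ube genes of ubiquitin transfer, 10 fell and none rose (median -0.34, adjusted p = 3.03e-05), whereas 14 Psmd genes of the proteasome did not shift (median 0.02, adjusted p = 0.7). Zinc finger genes named Zfp fell in 81 of 293 cases and rose in 9 (median -0.19, adjusted p = 1.08e-05).

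Other families shifted upward. Of 45 Krt genes, which encode keratins, 8 rose and none fell (median 0.37, adjusted p = 6.75e-05), and of 24 Klk genes of kallikrein proteases 4 rose and none fell (median 0.39, adjusted p = 0.00434). Of 1070 Olfr genes, the olfactory receptors, 47 rose and 5 fell (median 0.16, adjusted p = 0.00408). Their mean level was 7.71, and all genes of level group 2, at a mean level of 7.52, had a median of 0.17. The Olfr shift was thus no larger than that of genes of like level. The family tests did not take expression level into account. Sensory receptors and beta-defensins together made 1285 genes with a median of 0.16. The 471 of them at a mean log2 level of at least 8 had a median of 0.26, which became 0.18 after quantile normalization and 0.13 after cyclic loess. These 471 genes were also higher in undifferentiated replicate 3 than in replicates 1 and 2, by a median of 0.23, and differentiated cells exceeded replicate 3 by 0.08.

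Skeletal muscle and endothelial marker lists were higher in differentiated cells in camera, but neither shift passed with an estimated correlation (adjusted p = 0.403 for both). Against random lists matched on mean level their medians lay at percentiles 99.91 and 96.76. The medians of those random lists centred on 0.15 and 0.17, below the 0.43 and 0.33 of the marker lists. Both marker lists were picked for their camera calls on the same differences, and randomly drawn genes need not vary together as list members may. The percentiles therefore do not exclude the general shift of dim features as the cause. Against sensory receptor and beta-defensin genes of like level the marker lists lay at percentiles 99.94 and 95.15, with the same limits. The second is too close to 95 to set it apart from a shift of features of genes these cells are not thought to use. Of 8 abundant muscle or endothelial genes chosen beforehand, 2 rose (Ckm and Pecam1). Acta1 differed by 0.00 and Cdh5 was at or below the random probes in both groups. Myog (0.53, limma adjusted p = 0.0535), Mylpf (0.28, 0.118), Kdr (0.16, 0.394) and Egfl7 (-0.16, 0.473) did not pass. With 2 of 8 risen, these genes do not decide on cells of those types. All 8 are members of the 2 lists, so their count is no separate check of the list shifts. Replicate 3 lay above replicates 1 and 2 by a median of 0.32 on the muscle list and 0.08 on the endothelial list, and differentiated cells lay above it by 0.21 and 0.16; with 1 undifferentiated array in that comparison, cells of those types in the cultures, a modest rise within the osteoblasts and an array effect shared with replicate 3 cannot be told apart for either list, although less of the endothelial difference lay between the undifferentiated arrays.

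Undifferentiated replicate 3 lay nearer the differentiated arrays than replicates 1 and 2 did, at 0.85 of their mean distance. Over 56 genes at least 4-fold higher in differentiated cells than in replicates 1 and 2, the median share of differentiated RNA that would explain its values was 0.0147 (quartiles -0.00512 and 0.0496), which argues against mixed RNA. Quantile normalization moved the distance ratio to 0.888, and to 0.901 for the nearest case to equality among the differentiated arrays, so the shape of the intensity distribution accounts for part at most and is not settled. On the log2 scale replicate 3 stood at 0.0519 of the way toward differentiated cells over those 56 genes and at 0.136 over 43 genes that were lower, but at 0.664 and 0.447 over genes 1.4- to 2-fold higher or lower. As a covariate the array number start left 3065 genes changed. A partly differentiated culture and an effect of the array number cannot be told apart, because no other undifferentiated array shares that number start. The positions over genes 1.4- to 2-fold higher or lower do not decide between them. Those genes were sorted by the difference from replicates 1 and 2 that also sets the position. Noise in replicates 1 and 2 can move replicate 3 toward differentiated cells in this measure, most where the difference is small. Such noise would raise the low positions over genes changed at least 4-fold, not lower them. They leave room for only a small step toward differentiated cells at those genes, and they rest on 1 array.

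Cholesterol synthesis genes were lower in differentiated cells. Their median lay at percentile 0 of 10000 random lists matched on mean level, whose medians centred on -0.00529. Genes of like level thus shifted far less than the list's median of -0.57, which argues against a shift of features at that level as the cause. The percentile itself has limits, because the list was picked for its camera call on the same differences. Its genes also varied together (estimated correlation 0.38), as randomly drawn genes need not. Against replicate 3 alone the median was -0.334, and 17 of 23 genes were lower, just short of the 3 in 4 set beforehand for excluding the array number group. With the number start as a covariate 9 genes fell, none rose and the camera adjusted p was 0.000967, the highest of a range from 1.97e-08 over the settings run (adjusted p = 0.403 with an estimated correlation and no covariate). That comparison rests on 1 undifferentiated array, replicate 3, so the array number group and the untested effect of 15 days of differentiation cannot be told apart.

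The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For each of the 5 results below, 1 of the 10 splits, the real one, gave a value as large. The real split gave 8365 changed features, 1620 at 2-fold, 3367 changed genes and 617 at 2-fold, where the highest other split gave 0 for each. It gave 6 list shifts, where the highest other split gave 5, with undifferentiated replicates 1 and 2 and differentiated replicate 3 on one side. Any strong difference between the groups enters the spread within the other splits, so 0 changed features and genes there were largely fixed in advance. Image date followed the groups, so these counts do not tell it from differentiation.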
